A study of Mus musculus with 6 samples.

How the data were processed

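Gene expression was measured in left ventricular tissue of 10-week-old male C57BL/6 mice with 1 Affymetrix array per sample, 3 arrays of a saline group and 3 of a group given 2-methyl-2-thiazoline (2MT). Per the labels' protocols, 2MT was injected under the skin at 50 mg/kg and the hearts were taken 4 h later, RNA was extracted with Trizol, and biotinylated cDNA was made from 100 ng of total RNA. All 6 samples carry that protocol text, which describes only the 2MT injection, and their group comes from the treatment given in their labels. The labels do not state that each array stands for a separate animal. The p-values of single genes therefore measure only the spread between these samples, which may be technical.

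The deposited values are 1 number per probe set and array, taken as log2 signal. They run from 0.51 to 13.5 and the 6 array medians lie between 4.32 and 4.37. The base of the logarithm comes from that range, because a natural logarithm would exceed a scanner's range, and no header states it. Per the submitters' processing notes, MAS5 was used, with no version or role given. The normalization the authors applied is otherwise not given in the sources used here. The test had been planned for MAS5 signals on a linear scale, with log2 values to be used as given if the deposited table held them, and they were used as given, with no further scaling. No detection calls were used here, so signal over background is unknown, fold changes of dim genes may be understated, and the number of arrays limits the precision. For arrays there is no count depth.

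Probe sets were named through the platform's annotation. Of 28944 probe sets, 21789 had 1 gene symbol, 1621 several and 5534 none here. Of the first kind, 21698 matched the mouse gene table by Entrez ID and 0 symbols changed. They named 19938 genes, each represented by its probe set with the highest mean over the 6 arrays. Genes whose mean over the 6 arrays was under the median of all probe sets, 4.345, were left out as dim, which left 10547 genes. No coordinates are given because the sources used here name no genome build.

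The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend on mean signal, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all genes tested. Adjusted p values in the text come from limma, and a gene is said to have risen or fallen only with an adjusted p under 0.05. An exact permutation test of 3 against 3 cannot give a p below 0.1. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 3 tested genes, and again with the correlation estimated from the data and with fry. Camera compares a list's genes with the other tested genes. At the preset correlation it takes genes, rather than arrays, as its units, so its p-values do not measure the spread between samples. Fry tests whether a list's genes move one way on balance and compares them with no other genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

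Before the data were examined, the design, the alternatives, 41 gene lists of processes and cell types, and the rule for named genes were fixed. The rule names the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups do not overlap, up to 4 members with the smallest p of each list described, called members covered by a count of 5 or fewer, and a fixed set: Cirbp, Rbm3, Txnip, Pdk4, Hspa1a, Hspa1b, Fkbp5, Per1, Dbp, Nppa, Nppb, Mt1, Mt2, Txn1, Hmox1, Trpa1, Ucp3, Angptl4 and Cdkn1a. Of 857 list genes, 776 (90.5%) matched a probe set with 1 symbol, and 31 lay only on probe sets with several, among them Hspa1b and Cdkn1a, which are not reported here. Of the lists, 36 had at least 3 tested genes.

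The procedure was tested on simulated data made like the comparison of 2MT with saline, with 10547 genes of which 50 were changed at each size. It recovered 44% of 1.25-fold changes, 96% of 1.5-fold changes, and 100% of 2-fold and of 3-fold changes, with 11 false calls (6.08% of calls). The list test gave 5 of 100 random lists a p under 0.05 and 0 after adjustment. The simulated genes varied independently, so this does not show how the test fares where genes move together. On the real arrays, splits that mixed the groups gave up to 9 lists with the preset correlation.

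Alternatives changed 1 choice at a time: quantile normalization, median centring or cyclic loess, no dim filter or a stricter one, an offset before log2, the mean of a gene's probe sets, every probe set tested on its own, no variance trend, array weights, the replicate number as a block, each array left out, other thresholds, and, for lists, the tests named above and lists without members shared between lists.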

Results

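Left ventricles of mice injected with 2MT, a small thiazoline compound, were compared with left ventricles of the saline group, 3 arrays each. The aim was to learn what the compound changes in heart gene expression in a study of its cardioprotective mechanism. Groups are named as labelled, and no transcript measured here checks the labels. Arrays of 1 group correlated at 0.992 to 0.995 and arrays of different groups at 0.987 to 0.990, across the 10547 genes tested. Across all probe sets the ranges overlapped, at 0.993 to 0.995 and 0.992 to 0.994. Over the genes tested, the first principal component held 43.0% of the variance and separated the groups. Saline 3 stood apart on the second, which held 17.7%, at -11.6 against -1.12 to 4.65 for the other arrays. The mean of 2 erythrocyte markers, Alas2 and Bpgm, was 6.92 on saline 3 and 5.76 to 6.08 on the others.

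At 4 h, the strongest differences were lower levels in 2MT hearts of genes for antioxidant defence. Srxn1, which repairs overoxidised peroxiredoxins, was 6.76-fold lower, at a log2 signal of 5.50 ± 0.11 against 8.26 ± 0.24 in saline (SD, n = 3, adjusted p = 3.7e-09). Hmox1, the inducible haem oxygenase, was 5.72-fold lower, at 4.55 ± 0.17 against 7.06 ± 0.11. Its level in 2MT lay near the dim floor of 4.345. The highest rises were of Nppb, which encodes brain natriuretic peptide, at 3.33-fold (8.57 ± 0.36 against 6.83 ± 0.27), and of Cish, a suppressor of cytokine signalling, at 2.74-fold (7.61 ± 0.37 against 6.16 ± 0.19).

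Of 10547 genes, 488 passed an adjusted p of 0.05, 234 higher and 254 lower in 2MT. The groups did not overlap in 487 of them, and in 2229 genes (21.1%) of all tested, where chance gives 10%. Most differences were small: the median size was 0.40 on the log2 scale, 94 genes reached 1.5-fold (26 higher, 68 lower) and 22 reached 2-fold (2 higher, 20 lower). Leaving out saline 1, 2MT 2 or 2MT 3 gave 298, 276 and 262 genes, and a fit without the variance trend gave 292. Leaving out saline 3, the array apart on the second component, gave more, at 648 genes (312 higher, 336 lower).

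Targets of NRF2, the transcription factor of the antioxidant response, were lower as a list (camera adjusted p = 6.6e-34, and adjusted p = 0.0058 with an estimated correlation). Of 23 tested members, 15 fell and 0 rose (17 and 0 adjusted over the list alone), and all 23 had a lower mean in 2MT, with a median of -0.71. Besides Srxn1 and Hmox1, Gclc and Gclm, the subunits of the enzyme that limits glutathione synthesis, fell by 1.53 ± 0.08 and 1.49 ± 0.07 (SE). Osgin1 fell by 1.49 ± 0.13, to 4.24, under the dim floor, Gsta3, a glutathione transferase, by 1.26 ± 0.08, and Ftl1, the ferritin light chain, by 1.15 ± 0.06. The probe set of Ftl1 may also read near-identical copies of the gene.

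**Figure D1:**
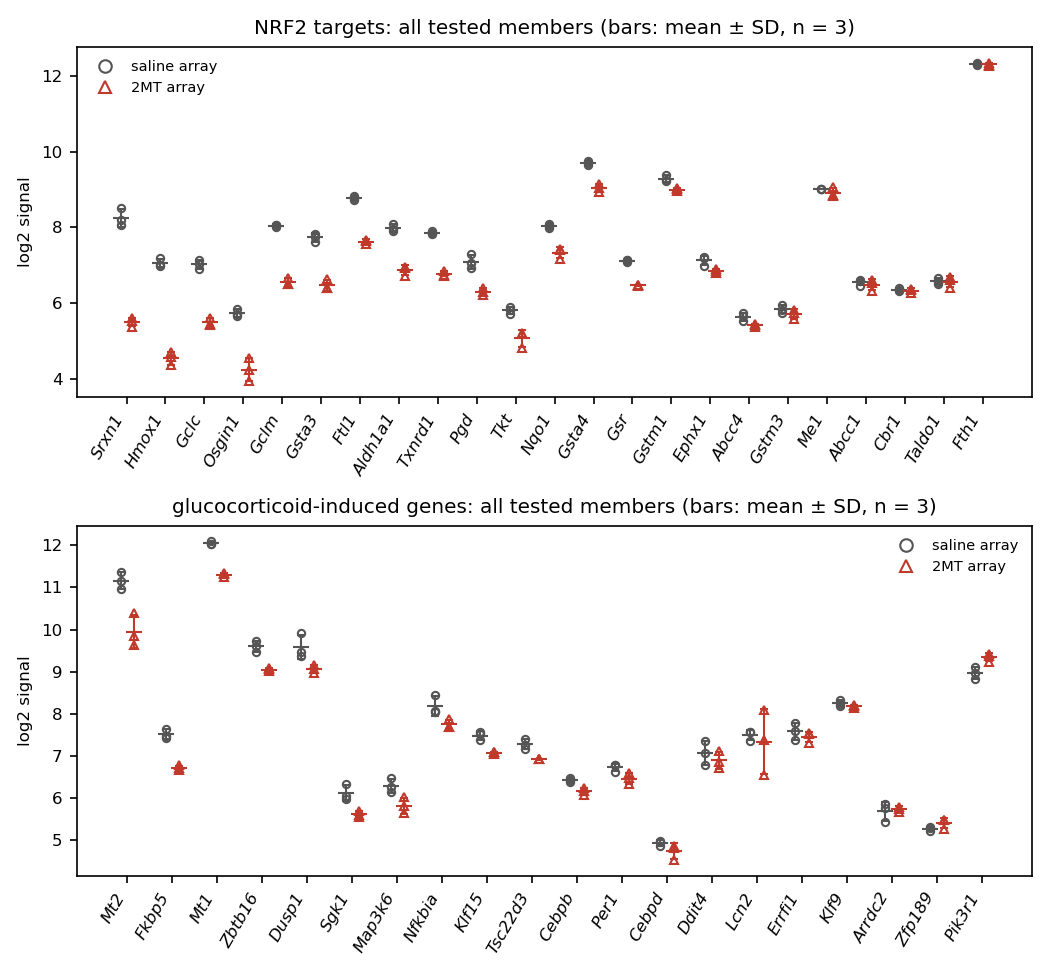
Log2 signal of each array for all tested NRF2 targets (top) and glucocorticoid-induced genes (bottom), ordered by the log2 difference. Circles are saline arrays, triangles 2MT arrays, and bars mean ± SD, n = 3; the 23 NRF2 targets all have the lower mean in 2MT, with Srxn1 at 5.50 against 8.26.

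The list of thioredoxin and glutathione systems, which shares members with the NRF2 list, was lower by the same test (adjusted p = 1.1e-06, and 0.048 with an estimated correlation). Of 25 tested members 8 fell and 1, Gpx3, rose (9 and 1 adjusted over the list alone). Gpx3 was not among the genes run through the alternatives. Its median of -0.06 was small beside its mean of -0.34. Without members shared between lists its mean went from -0.34 to -0.05 and its adjusted p was 0.20. Txnrd1, thioredoxin reductase, fell by 1.09 ± 0.06 (SE). Thioredoxin itself, Txn1, fell by 0.26 ± 0.05 with an adjusted p of 0.012, which became 0.059 without saline 1, 0.079 without 2MT 3 and 0.097 without the variance trend. Txnip, the thioredoxin-interacting protein, was at 10.30 ± 0.34 in 2MT and 10.66 ± 0.16 in saline (SD, n = 3, adjusted p = 0.13). Its log2 difference ran from -0.51 to -0.18 over the alternatives, and it passed in 1 of 16 (adjusted p = 0.022 in limma).

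Glucocorticoid-induced genes were lower as a list, with a median of -0.32 (camera adjusted p = 8.9e-11, and adjusted p = 0.030 with an estimated correlation). Of 20 tested members 10 fell and 1, Pik3r1, rose (12 and 1 adjusted over the list alone). Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, rose by 0.38 ± 0.07 (SE), and its adjusted p was 0.056 without the variance trend. Fkbp5, a co-chaperone of the glucocorticoid receptor, fell by 0.79 ± 0.07, the transcription factor Zbtb16 by 0.55 ± 0.06, and the metallothioneins Mt2 and Mt1 by 1.21 ± 0.14 and 0.75 ± 0.04. Per1 was at 6.47 ± 0.14 in 2MT against 6.73 ± 0.09 in saline (SD, n = 3, adjusted p = 0.096).

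The following lists passed the preset test and lost the call with an estimated correlation. In the metallothionein and metal handling list 3 of 6 tested members fell (3 over the list alone), with an adjusted p of 3.0e-04, and adjusted p = 0.12 with an estimated correlation. Without members shared between lists its mean went from -0.46 to -0.20 and its adjusted p was 0.36. They were Mt1, Mt2 and Slc40a1, the iron exporter ferroportin, which fell by 0.94 ± 0.12 (SE). In the FOXO, atrophy and autophagy list 5 of 25 fell (6 over the list alone), with adjusted p = 6.4e-05, and adjusted p = 0.14 with an estimated correlation. Fbxo32, an atrophy-linked ubiquitin ligase subunit, fell by 0.62 ± 0.08, Gabarapl1 by 0.68 ± 0.08, Sqstm1, an autophagy receptor, by 0.53 ± 0.06, Klf15 by 0.40 ± 0.07, and Map1lc3a by 0.21 ± 0.05. The call of Map1lc3a was lost without saline 1 or 2 or any 2MT array, at adjusted p values of 0.135, 0.0701, 0.0779, 0.13 and 0.105 in that order, and with median centring (0.0513), no dim filter (0.0583) or no variance trend (0.147).

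Of 14 tested inflammatory and acute phase genes, 3 fell (5 over the list alone), with adjusted p = 0.0017, and adjusted p = 0.13 with an estimated correlation. They were Ptgs2, the inducible cyclooxygenase, which fell by 1.13 ± 0.09, Il4ra, which fell by 0.67 ± 0.08, and Nfkbia, which fell by 0.43 ± 0.10 (SE). Nfkbia lost its call without saline 1 (0.0541), 2MT 1 (0.0754), 2MT 2 (0.0984) or the variance trend (0.0899). Of 10 tested cAMP and CREB targets, Pde4d, Sik1 and Rgs2 fell and Ppargc1a rose, 3 and 1 (4 and 1 over the list alone), with adjusted p = 0.0020, and adjusted p = 0.14 with an estimated correlation. Without members shared between lists its mean went from -0.18 to -0.03 and its adjusted p was 0.88. Ppargc1a, a coactivator of mitochondrial biogenesis, rose by 0.51 ± 0.07 (SE). Sik1 lost its call without saline 1 (0.0561), saline 2 (0.0613), 2MT 1 (0.0596) or the variance trend (0.0505). Of 19 tested immediate early genes Myc, Klf6 and Dusp1 fell, 3 (4 fell and 3 rose over the list alone), with adjusted p = 0.043, and adjusted p = 0.48 with an estimated correlation. Myc fell by 1.44 ± 0.13, to 4.16, under the dim floor, and Klf6 by 0.62 ± 0.08. Dusp1 lost its call without 2MT 3 (0.0541) or the variance trend (0.0668). The list lost its own without saline 1 (0.0901), saline 2 (0.0992) or 2MT 1 (0.0931), without members shared between lists (0.17) and with fry (0.18).

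Ion channel and calcium handling genes were higher as a list with a median of 0.07 (adjusted p = 0.015, and adjusted p = 0.14 with an estimated correlation). Gja1 and Kcnj11 rose, 2 of 25 tested (5 rose and 1 fell over the list alone). The list lost its call without saline 1 (0.0573), under quantile normalization (0.0531) and without members shared between lists (0.062). Ribosomal protein genes had a median of -0.07 over 28 tested (adjusted p = 0.019, and adjusted p = 0.70 with an estimated correlation), with 1 rise, Rpl10a, and 1 fall, Rplp1 (1 and 3 over the list alone). That list lost its call without saline 1 (0.0838) or 2MT 2 (0.228) and with fry (0.31). Of 4 tested adipocyte markers 1, Cidea, fell (2 over the list alone), with adjusted p = 0.035, and adjusted p = 0.33 with an estimated correlation. It lost its call without saline 1 (0.108), 2MT 1 (0.057) or 2MT 3 (0.082), without members shared between lists (0.12) and with fry (0.096). With no dim filter, which adds its 8 dim members, its mean went from -0.15 to -0.0014 and its adjusted p was 0.70. Calls of single genes were lost with 1 array left out, at these adjusted p values: Gja1 without saline 1 (0.0798), 2MT 2 (0.0897) or 2MT 3 (0.0814), and Kcnj11 without saline 1 (0.0728), saline 2 (0.111), saline 3 (0.0821), 2MT 1 (0.15) or 2MT 3 (0.175). Rpl10a lost its call without saline 2 (0.0719), 2MT 2 (0.0708) or 2MT 3 (0.0795), and Rplp1 without saline 1 (0.0992), 2MT 2 (0.108) or 2MT 3 (0.0569). Cidea lost its call without saline 1 (0.166), saline 2 (0.0558), saline 3 (0.0571), 2MT 1 (0.143), 2MT 2 (0.0524) or 2MT 3 (0.173), and with quantile normalization (0.0513), median centring (0.0538) or no dim filter (0.075). Without the variance trend Gja1 (0.0872), Kcnj11 (0.0954), Rpl10a (0.135), Rplp1 (0.175) and Cidea (0.113) did not pass, nor did Kcnj11 with no dim filter (0.0738) or Rplp1 with the mean of its probe sets (0.0536).

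**Figure D2:**
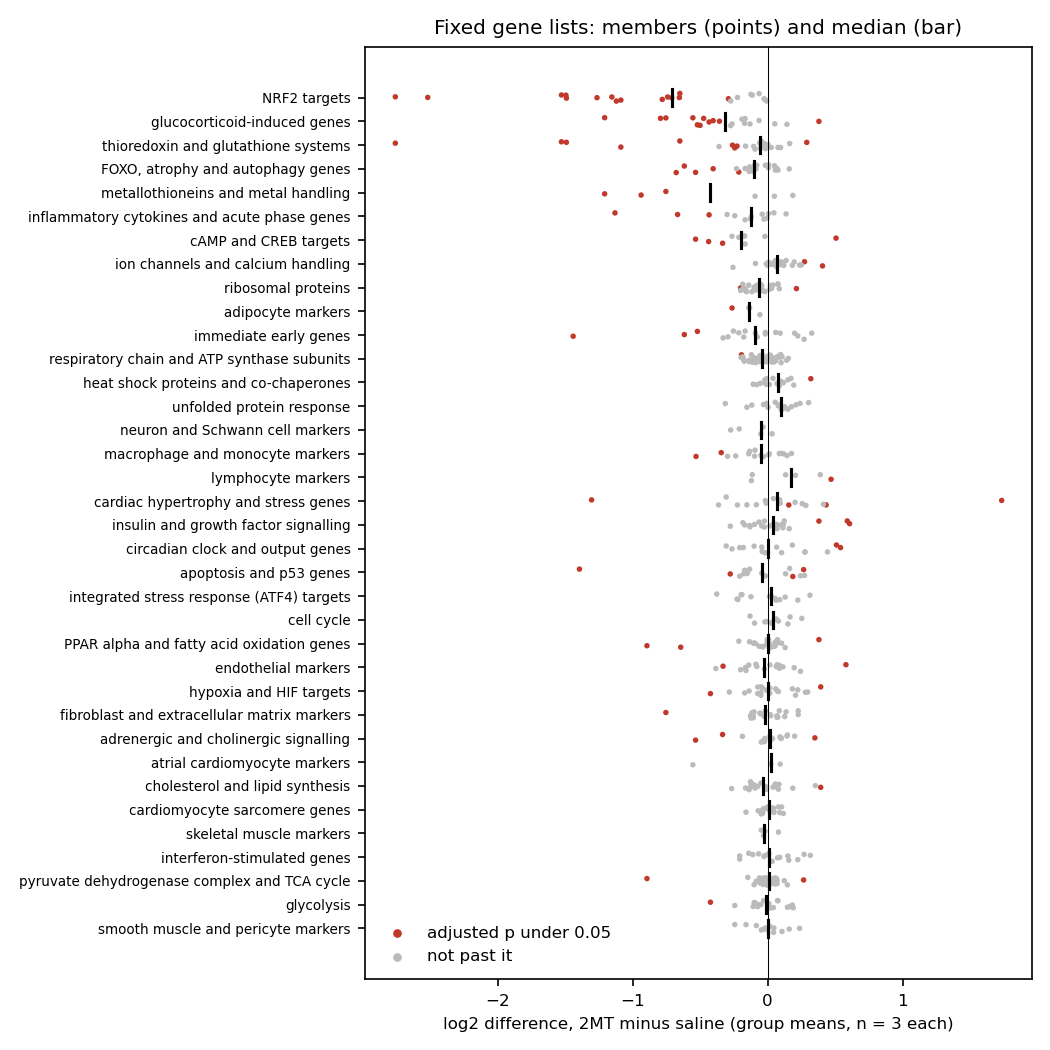
Log2 difference (2MT minus saline group means, n = 3 each) of every tested member of the 36 tested lists, with points for genes and a bar for the list median. Points of genes past adjusted p 0.05 are dark red; the NRF2 list has a median of -0.71 and the sarcomere list of 0.01.

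Genes of fuel use changed one by one rather than as lists. Pdk4, the kinase that inhibits pyruvate dehydrogenase, fell by 0.89 ± 0.08 (SE), to 10.92 ± 0.22 from 11.82 ± 0.08 (SD, n = 3), and Ucp3, a mitochondrial uncoupling protein, fell by 0.64 ± 0.12. Of 27 tested PPAR alpha and fatty acid oxidation genes, Pdk4 and Ucp3 fell and Acot2 rose (adjusted p = 0.64). Of 29 genes of the pyruvate dehydrogenase complex and TCA cycle, Pdk4 fell and Pdp1 rose (adjusted p = 0.93), and of 20 glycolysis genes Slc2a1, a glucose transporter, fell (adjusted p = 0.93). Of 54 respiratory chain and ATP synthase subunits Cox4i1 fell (adjusted p = 0.057). That list passed under quantile normalization (0.015), cyclic loess (0.0013) and the mean of a gene's probe sets (0.030), and without saline 2 (0.0363), 2MT 1 (0.0271) or 2MT 3 (0.0355). Adjusted over the list alone, the counts of rises and falls were 1 and 2, 1 and 1, 2 and 1, and 1 and 5 in these lists, in the order given. Acot2 lost its call without saline 1 (0.175), saline 2 (0.0734), 2MT 2 (0.202) or 2MT 3 (0.114), and Pdp1 without saline 1 (0.11), saline 2 (0.0583), 2MT 2 (0.122) or 2MT 3 (0.122). Cox4i1 lost its call without saline 1 (0.121), saline 2 (0.0728), 2MT 1 (0.0621), 2MT 2 (0.127) or 2MT 3 (0.0842). Without the variance trend Acot2 (0.165), Pdp1 (0.0976) and Cox4i1 (0.184) did not pass, nor did Acot2 with cyclic loess (0.0634) or no dim filter (0.076) or Cox4i1 with median centring (0.0515). Angptl4 was at 5.61 ± 0.19 in 2MT and 5.70 ± 0.09 in saline (SD, n = 3, adjusted p = 0.71).

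Of 18 tested cardiac hypertrophy and stress genes, Nppb, Xirp1 and Fhl2 rose and Ccn2 fell (6 and 2 over the list alone), and the list did not pass (adjusted p = 0.28). Ccn2, a matricellular growth factor, fell by 1.30 ± 0.08 and its relative Ccn1 by 1.20 ± 0.08 (SE). Fhl2 lost its call without saline 1 (0.11), saline 2 (0.15), 2MT 1 (0.155), 2MT 2 (0.0753) or 2MT 3 (0.144), and with quantile normalization (0.0789), median centring (0.0606), cyclic loess (0.0972), no dim filter (0.0756) or no variance trend (0.266). Nppa, the atrial peptide gene, was at 10.33 ± 0.16 in 2MT and 10.24 ± 0.34 in saline (SD, n = 3, adjusted p = 0.77).

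The remaining large rises were of Rasl11b (0.95 ± 0.08, SE), Dusp7, a phosphatase of ERK (0.89 ± 0.07), Itgb6 (0.87 ± 0.09), Socs2, another suppressor of cytokine signalling (0.81 ± 0.11), Ccdc141 (0.78 ± 0.12), Ppargc1b, a relative of Ppargc1a (0.76 ± 0.09), Sox4 (0.76 ± 0.13), Nrp1 (0.74 ± 0.06), Pirt (0.72 ± 0.11) and B3galt2 (0.70 ± 0.12). In saline, Sox4, B3galt2 and Pirt lay near the dim floor of 4.345, at means of 4.45, 4.51 and 4.72. The remaining large fall was of Trp53inp1, a p53-inducible gene, which fell by 1.39 ± 0.08. Trpa1, an ion channel, was under the dim filter, at 1.97 ± 0.32 in 2MT and 1.96 ± 0.38 in saline.

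**Figure D3:**
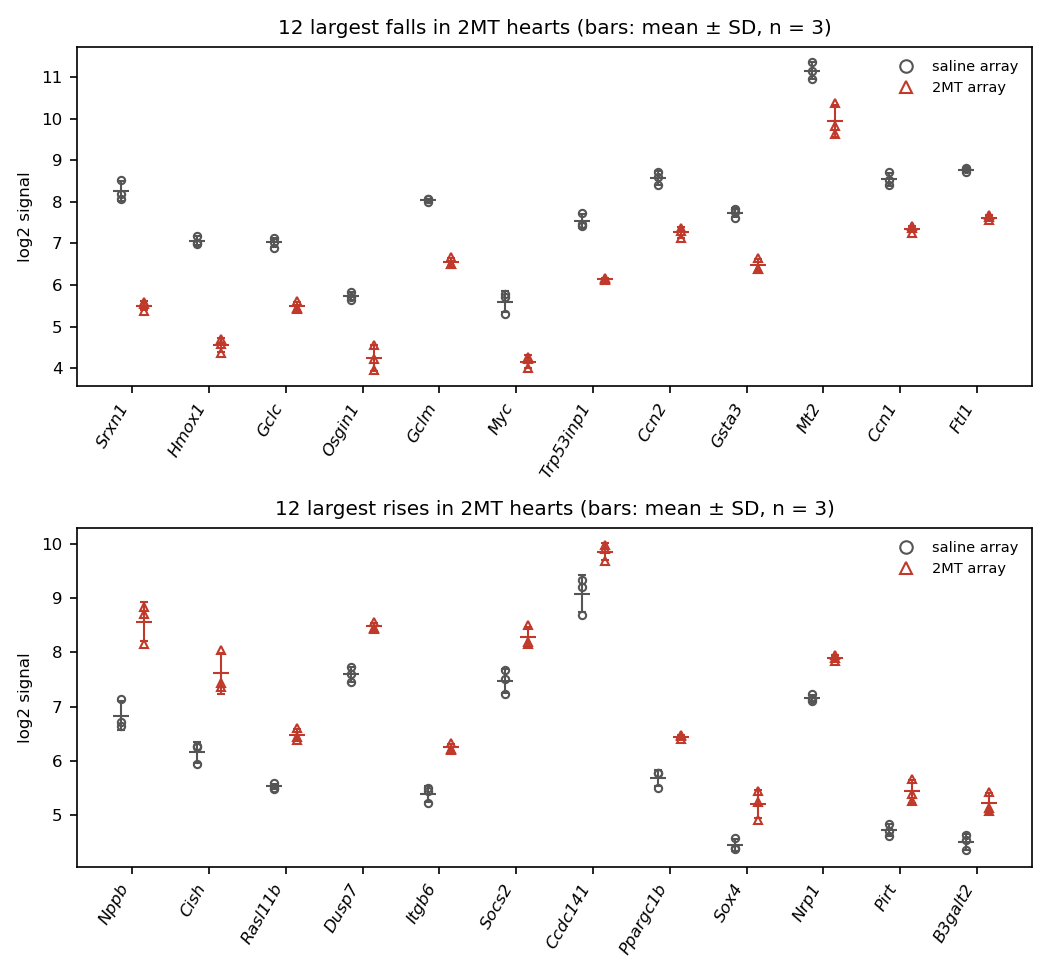
Log2 signal of each array for the 12 genes with the largest falls (top) and the 12 with the largest rises (bottom). Circles are saline arrays, triangles 2MT arrays, and bars mean ± SD, n = 3. Only called genes whose groups do not overlap could be picked, and Nppb lies at 8.57 in 2MT against 6.83 in saline.

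Besides the adipocyte markers, with a median of -0.14, no list of cell type markers passed. Of 22 sarcomere genes of cardiomyocytes 0 rose or fell in limma (3 at an unadjusted p under 0.05), and their median difference was 0.01. The medians were -0.02 for 21 fibroblast genes, of which Thbs1 fell, -0.02 for 19 endothelial genes, of which Aplnr rose and Pecam1 fell, and -0.05 for 17 macrophage genes, of which Fcgr3 and Lyve1 fell. Of 13 smooth muscle, 5 neuron and Schwann cell, 4 skeletal muscle and 3 atrial genes 0 changed (1, 2, 0 and 0 at an unadjusted p under 0.05), and of 6 lymphocyte genes, with a median of 0.17, H2-Ab1 rose. Adjusted over the list alone, 1 smooth muscle gene rose, 1 neuron gene fell, and 2 endothelial genes fell, the other counts staying as given. The camera adjusted p values were 0.18 for the macrophage list, 0.18 for the neuron list, 0.22 for the lymphocyte list and between 0.66 and 0.95 for the others. The macrophage list passed without 2MT 1 (0.0261) and the lymphocyte list without saline 2 (0.0363) and with the stricter dim filter (0.0403). Aplnr lost its call without saline 2 (0.0748) or 2MT 1 (0.0659), and H2-Ab1 without 2MT 1 (0.068), 2MT 2 (0.0876) or 2MT 3 (0.117). Pecam1 lost its call without saline 1 (0.0936), saline 2 (0.0858), 2MT 2 (0.092) or 2MT 3 (0.112), and Lyve1 without saline 1 (0.0894), saline 3 (0.0757), 2MT 1 (0.0691), 2MT 2 (0.147) or 2MT 3 (0.115). Without the variance trend H2-Ab1 (0.0832), Pecam1 (0.0891) and Lyve1 (0.119) did not pass, nor did Lyve1 with no dim filter (0.0594).

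Both cold-inducible RNA-binding protein genes were lower without passing: Cirbp was at 6.59 ± 0.06 against 6.80 ± 0.05 (adjusted p = 0.11) and Rbm3 at 9.62 ± 0.13 against 9.84 ± 0.10 (SD, n = 3, adjusted p = 0.097). Adjusted over the list alone, both of these 2 genes passed. With the replicate block Rbm3 passed (0.035) and Cirbp did not. Of 20 tested heat shock genes 1, Dnajb1, rose (1 also adjusted over the list alone), with adjusted p = 0.10 for the list. Its call was lost without saline 1 (0.0787), saline 2 (0.104), saline 3 (0.0964), 2MT 2 (0.148) or 2MT 3 (0.219), and with quantile normalization (0.0513), median centring (0.0606), no dim filter (0.0798) or no variance trend (0.0658). Hspa1a was at 5.25 ± 0.16 in 2MT and 5.35 ± 0.26 in saline (SD, n = 3, adjusted p = 0.73). Of 19 genes of the unfolded protein response 0 passed in limma, also adjusted over the list alone, with 7 at an unadjusted p under 0.05, and the list (adjusted p = 0.10) passed without 2MT 2 (0.0017), with no dim filter (0.0314) and with the stricter dim filter (0.0403). The heat shock list passed without 2MT 2 (0.0133) and with no dim filter (0.0288).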

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

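Both results here come from fits planned before the data were examined, on data the comparison of named genes left out. Among 2756 probe sets with several gene symbols or none here, 82 passed an adjusted p of 0.05 when every probe set was tested on its own, 34 higher and 48 lower in 2MT. Of these, 38 had several symbols, of 890 tested, and 44 had none, of 1866. They are named by no gene.

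Among 9391 genes under the dim filter, 22 passed an adjusted p of 0.05 in limma when no filter was applied, 4 higher and 18 lower. Clec4d, a neutrophil marker, had the smallest p among them and fell by 1.23, from 4.58 to 3.35. Nr4a3, an immediate early gene, fell by 0.79, and Cbr3, an NRF2 target, by 0.76. These 3 are members of fixed lists, picked for naming after their values were seen. Groups of 3 samples are too small for the test of single outlying arrays.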

How the results depend on the processing

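All alternatives were planned before the data were examined. The 488 genes (234 higher, 254 lower) became 292 (124 and 168) without the variance trend, 94 (26 and 68) with a 1.5-fold minimum at either an unadjusted or an adjusted p of 0.05, and 768 (393 and 375) at an adjusted p under 0.10; fewer or more genes meet such thresholds by construction, and the cause of the first change was not tested. Leaving out 1 array gave 262 to 648 genes, 101 to 312 higher and 155 to 336 lower, with fewer samples in each fit. The counts were 298 without saline 1, 276 without 2MT 2 and 262 without 2MT 3. The highest, 648, came without saline 3, and 434 of these were shared with the main fit. The other settings gave 409 to 582 genes apart from the block. The labels do not state that the numbers in the titles pair the arrays. Same-numbered deviations correlated weakly, at 0.07, 0.04 and 0.02, but 5 of 6 arrays correlated best with their own number. Whether the arrays are paired is left open. With the replicate block, 586 genes passed, 481 of them shared with the fit without it, and 11 lists; of the named genes Dnajb1 no longer passed (0.056), and Rbm3 (0.035), Sox17 (0.048), Osmr (0.036), Uqcrq (0.030), Ndufs4 (0.039) and Pdia3 (0.040) did. The 11 lists became 3 with an estimated correlation, 5 without members shared between lists, and 7 to 12 on leaving out 1 array (7 without saline 1). The causes were not tested. The estimated correlation of the lost metallothionein, inflammatory and ion channel lists was under the preset, at -0.07, -0.04 and -0.013. A higher correlation between genes thus did not cost these lists their calls. In the lost FOXO, cAMP, immediate early, ribosomal and adipocyte lists it was above the preset, at 0.04, 0.03, 0.07, 0.29 and 0.10. In the NRF2 list it was under the preset, at -0.016, and the camera adjusted p still went from 6.6e-34 to 0.0058. The 2 settings thus differ in more than the correlation, since the preset test takes genes as its units. A lost call is therefore no measure of correlation in any of these lists. The NRF2 and glucocorticoid lists passed in all 19 alternatives run for lists, with means of -0.84 to -0.64 and -0.37 to -0.29 and adjusted p values up to 0.0058 and 0.030. Of 75 called genes among the 160 named and tested, 47 passed in all alternatives run per gene. Across alternatives, named genes lost a call 138 times and gained one 42 times, and lists 28 and 16 times. In 5 of the called genes with several bright probe sets (39), Eif4e, Lztfl1, Myo18b, Qk and Tmod1, the probe sets went in opposite directions. No detection call was used here, so what background limits is unknown.

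Signs turned 18 times in 11 named genes and 38 times in 12 lists, and in 0 of these cases was the result past the threshold in either setting; the cause was not tested. On leaving out 1 array the log2 difference ran from -0.79 to 0.17 for Alas2, -0.54 to 0.23 for Lcn2, -0.24 to 0.0083 for Bpgm, -0.26 to 0.01 for Apoa2, -0.20 to 0.042 for Hspa1a, -0.17 to 0.015 for Angptl4, -0.13 to 0.10 for Sox10, -0.13 to 0.055 for Tnni2 (0.014 with array weights), -0.19 to 0.08 for Casq1, -0.037 to 0.075 for Stard10 and -0.07 to 0.27 for Nppa. List means ran from -0.036 to 0.012 for glycolysis, -0.017 to 0.029 for adrenergic, -0.023 to 0.0042 for lipid synthesis, -0.0048 to 0.015 for sarcomere, -0.058 to 0.0062 for fibroblast, -0.066 to 0.029 for endothelial, -0.021 to 0.019 for smooth muscle and -0.045 to 0.023 for skeletal muscle genes. With the stricter dim filter they were 0.0057 for glycolysis, -0.0041 for hypoxia, 0.0033 for the integrated stress response and 0.011 for lipid synthesis. With no dim filter they were -0.014 for the cell cycle and 0.026 for skeletal muscle. With quantile normalization they were -0.0030 for adrenergic and -0.019 for sarcomere genes, and with cyclic loess -0.0063, -0.025 and, for smooth muscle, -0.0066. With array weights they were -0.0035 for smooth muscle and 0.0077 for skeletal muscle. Without members shared between lists they were 0.0017 for glycolysis, 0.018 for the TCA cycle, -0.026 for smooth muscle and 0.01 for skeletal muscle.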

Other observations

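The tests for scaling, macrophages, exchanged arrays, exchanged groups, metallothioneins and time of day were chosen after the results they bear on had been seen. The tests of other splits and of the 3 added lists were written before their results were seen, the added lists after the gene changes that prompted them.

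Several lists described by few genes did not pass as lists. Of 23 tested insulin and growth factor genes, Irs1 (0.61 ± 0.08, SE), the growth factor Fgf16 (0.59 ± 0.07) and Pik3r1 (0.38 ± 0.07) rose and 0 fell, and 3 and 0 adjusted over the list alone. The camera adjusted p was 0.34, and fry, which compares with no other genes, gave an adjusted p of 0.022. Fry called 10 lists, and of the 11 called with camera it lost the immediate early (0.18), ribosomal (0.31) and adipocyte (0.096) lists. Irs1 lost its call with the mean of its probe sets, at an adjusted p of 0.13, and Pik3r1 without the variance trend, at 0.056. Of 17 clock and output genes, the repressors Bhlhe40 (0.54 ± 0.11) and Bhlhe41 (0.51 ± 0.11) rose (5 rose and 1 fell adjusted over the list alone; adjusted p = 0.41 for the list), and each lost its call on leaving out single arrays: Bhlhe40 without saline 1 (0.0572), 2MT 1 (0.0621) or 2MT 2 (0.0654), Bhlhe41 without 2MT 2 (0.0654) or 2MT 3 (0.0648), and without the variance trend (0.0511). Dbp was at 7.79 ± 0.18 in 2MT and 7.35 ± 0.35 in saline (SD, n = 3, adjusted p = 0.086). Saline 3 was at 7.75 and the other saline arrays at 7.15 and 7.14. Over the alternatives Dbp passed in 1 of 16, the fit without saline 3 (log2 difference 0.645, adjusted p = 0.0017 in limma).

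Of 17 adrenergic and cholinergic genes, Chrm2, the cardiac muscarinic receptor, rose by 0.35 ± 0.06 and Pde4d and Rgs2 fell, by 0.53 ± 0.07 and 0.33 ± 0.06 (2 rose and 2 fell adjusted over the list alone; adjusted p = 0.88 for the list). Of 15 apoptosis and p53 genes, Ccng1 and Mcl1 rose and Trp53inp1 and Fas fell (3 and 3 adjusted over the list alone; adjusted p = 0.55, and 0.036 with fry). Of 22 hypoxia genes Vegfa rose and Slc2a1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.81), and of 22 lipid synthesis genes Agpat2 rose (1 adjusted over the list alone, adjusted p = 0.88). Ccng1 lost its call without saline 1 (0.119), saline 2 (0.109), 2MT 1 (0.0632), 2MT 2 (0.0897) or 2MT 3 (0.138), and Fas without saline 1 (0.103), saline 2 (0.0512), 2MT 1 (0.0621), 2MT 2 (0.0805) or 2MT 3 (0.105). Mcl1 lost its call without saline 1 (0.131), 2MT 1 (0.113) or 2MT 3 (0.166), Vegfa without 2MT 1 (0.0624) or 2MT 3 (0.0653), and Agpat2 without 2MT 2 (0.0614). Without the variance trend Ccng1 (0.209), Fas (0.0704), Mcl1 (0.124) and Vegfa (0.0754) did not pass, nor did Ccng1 with cyclic loess (0.0523) or Mcl1 with no dim filter (0.0532). Of 17 interferon, 14 integrated stress response and 11 cell cycle genes 0 passed in limma (3, 4 and 2 at an unadjusted p under 0.05; adjusted p of the lists 0.88, 0.61 and 0.63). The median and mean differ in sign for the integrated stress response, TCA cycle and atrial lists. Besides the cold-inducible pair, lists with under 3 tested genes were not tested, and 0 of their members above the dim filter passed in limma or at an unadjusted p under 0.05: erythrocyte (Alas2 and Bpgm), mesothelial (Wt1 and Krt8), neutrophil (Lcn2), and thymus, lung and liver (Apoa2). Clec4d, a neutrophil marker under the filter, passed when no filter was applied.

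The fall of NRF2 targets, with a median of -0.71, was set against technical explanations. A scaling error, also one that depends on brightness, moves genes of like signal alike. The list members differed from the 200 genes nearest in mean signal by a median of -0.72, with quartiles of -1.22 and -0.18. A first comparison, with the median of all genes, was void because the deposited arrays share their medians. It was replaced by this one after the results were seen. Fewer macrophages would lower their markers at least as much, and these had a median of -0.05 with quartiles of -0.14 and 0.09. Of the 17 markers 10 were lower and 7 higher, and Fcgr3 and Lyve1 fell, by 0.53 and 0.34. A median over mixed markers cannot show whether some of these cells were fewer. Single arrays exchanged between the groups need an array of each group out of place. Here 0 of 6 had a list mean nearer to the other group (7.59 to 7.62 in saline, 6.77 to 6.80 in 2MT). The list was taken up because it differed between the labelled groups, so these means are no independent check. A bound over all probe sets, the lowest correlation within groups above the highest between them, was tried and not met (0.9932 against 0.9936). On average 0 of 6 arrays correlated better with the other group over all probe sets. Over the genes tested the ranges did not overlap, at 0.992 to 0.995 within and 0.987 to 0.990 between groups. An exchange of the labels of both groups as a whole cannot be told apart from an effect of 2MT, since it leaves every value in place and turns every sign. Cirbp at -0.21 and Rbm3 at -0.22 did not pass in the main fit and decide nothing. 2MT may thus have lowered or, with labels exchanged, raised the NRF2 targets.

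The fall of glucocorticoid-induced genes was not carried by the metallothioneins alone, since the list without Mt1 and Mt2 kept a median of -0.27 over 18 genes. Excision at different times of day cannot be told apart from an effect of 2MT here. The medians of clock output and antiphase genes differed by 0.21, at 0.10 and -0.10, between the bounds set for either reading, and the labels give no time of excision. An exchange of both groups' labels stays open here too.

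There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 488 genes and the highest other 0, so 1 of the 10 gave as many genes. It gave 11 lists with the preset correlation and the highest other 9, so 1 of the 10 gave as many lists. With an estimated correlation the real split gave 3 lists and the others 0.

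Each of 3 hypotheses was tested on a set of genes outside the fixed lists, and none of the 3 sets moved as predicted. Members of the fixed lists were left out, so the sets do not cover every known target. Lower Ccn1 and Ccn2 raised the hypothesis of lower YAP and TEAD activity, and 15 other targets had a median of 0.01 (camera gave 0.44 unadjusted, and an adjusted p of 0.66 over the 3 lists). Lower expression of other phase II and detoxification enzymes was not found in 19 genes, with a median of -0.02 (0.25 unadjusted, adjusted p 0.66), although Esd and Mgst1 fell. Higher ERK feedback expression beside Dusp7 was not found in 10 genes, with a median of 0.01 (0.73 unadjusted, adjusted p 0.73).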
